A study of Homo sapiens with 8 samples.

How the data were processed

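MicroRNA (miRNA) levels were measured in 8 samples of mammospheres, the floating clusters that mammary cells form in ultralow attachment culture, each on its own one-colour Agilent human miRNA array. Per the labels, total RNA was extracted with TRIzol and labelled with the dye Cy3-pCp. The labels give 2 untreated samples each of 3 cell lines. MCF10A is an immortalised, non-tumour mammary epithelial line, and MCF7 is an oestrogen receptor-positive breast cancer line. The other line is named only MDA in the labels, without its full designation. A further MCF7 sample was treated with paclitaxel at 100 nM, and another with 5-fluorouracil (5FU) at 50 mg/ml as the label states it. Per the labels, each drug was given for 48 h after 3 days in culture.

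Per the submitters' processing notes, the images were read with Agilent Feature Extraction 10.7.3.1. The deposited scanner files hold spot intensities on a linear scale, with gProcessedSignal as the background-subtracted intensity, per the file headers and columns. Each array carries 48200 spots for human miRNAs, from 3101 probes of 1205 human miRNAs. The authors also deposited a table of values on the log2 scale. All of its columns have the same median, 3.43. Across miRNAs they correlate at r of 0.991 to 0.999 with log2 of the total gene signal that Feature Extraction gives for the same array, so scale and direction are known. Its columns were taken as log2 quantile-normalized signal, but the authors' normalization was not reproduced here, and whether an offset was added is not known. That table served only as an alternative. All arrays were on 1 slide and in 1 scan, 4 in each of 2 slide rows, and each row held 1 array of each untreated line and 1 drug array.

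From the intensities, control spots and spots marked as outliers were left out and the spots of a probe were averaged. Each array was divided by its 75th percentile over the 292 human probes well above background on all 8 arrays. A probe counted as well above background on an array where more than 50% of its spots were marked so by Feature Extraction. A floor was then set at the 5th percentile of the scaled signals of probes well above background (log2 −5.78), and log2 was taken. Each miRNA was represented by its brightest probe and tested where that probe was well above background on at least 2 of the 8 arrays, which left 320 human miRNAs. Other probes of the called miRNAs, where measured on all 4 arrays of a comparison, had the same sign for 52 of 52 in MCF7 against MCF10A, 21 of 21 in MDA against MCF10A and 41 of 42 in MDA against MCF7. The array's 422 probes for 142 viral miRNA names stayed outside the tests, and 27 of these names were above background on at least 1 array: 25 on MCF10A replicate 2, 16 on MDA replicate 1 and 9 to 13 on each other array. miRNA names are those of the array's design, and 8 list members known by another name were matched to them. miR-106a-5p was not analysed here. No coordinates are given because no genome build was used.

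The signal behind the values differed between arrays. The 75th percentile ranged from 817 (MDA replicate 1) to 2227 (paclitaxel), and 221 (MDA replicate 1) to 302 (MCF10A replicate 2) human miRNAs were well above background. The median coefficient of variation between spots of 1 probe was 5.39% to 7.19%. The number of arrays limits the precision. The labels do not say that the samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

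All 8 arrays entered 1 linear model with 5 groups (lmFit and eBayes, limma 3.58.1 in R 4.3.3; files were read with the R package data.table, version 1.17.8), with 3 residual degrees of freedom, all from the untreated pairs. Each drug group has 1 array and was assumed to vary like those pairs. A pair with both arrays at the floor adds no spread, which can make a p-value too small, also in a fit without an array. At least 1 untreated pair was at the floor for 36 of the 107 miRNAs called in MCF7 against MCF10A, 23 of 48 in MDA against MCF10A and 42 of 115 in MDA against MCF7. A miRNA was called where its Benjamini-Hochberg adjusted p was under 0.05. Every adjusted p for a single miRNA comes from this limma model. The 3 contrasts between untreated lines, each drug against untreated MCF7, the mean of both drugs against untreated MCF7, and 5FU against paclitaxel were tested. Where a miRNA was well above background on both arrays of one group and on no array of the other, its difference is given as "at least N-fold": the mean of the brighter group over the mean of, per array of the other group, the highest of the probe's own signal, the lowest signal of any probe well above background and the floor.

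The model was tested on simulated data for 320 miRNAs, of which 100 were changed, in 20 simulations. For MCF7 against MCF10A it recovered 43.1% of changes of 1 log2 unit and 78.4% of changes of 2 log2 units, with 2.3 false calls on average. For 5FU against untreated MCF7 it recovered 23.3% and 65.6%, with 1.4 false calls. The simulated noise was normal and independent between miRNAs, and no floor was applied. These rates therefore do not cover calls with a pair at the floor or correlation between miRNAs.

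The model, the thresholds, 32 lists of miRNAs (families, genomic clusters, miRNAs induced by p53, entries prone to technical variation and markers of other cell types) and most alternative settings were fixed before the data were examined. Lists with at least 3 tested members, 24 in all, were tested with camera at a preset correlation of 0.01 between miRNAs, and also with an estimated correlation and with fry. The correlation was estimated from 3 residual degrees of freedom, so that version has little power, and a list not called by it is left undecided. The miRNAs named below were chosen by a rule. In each comparison these are the 10 called miRNAs with the largest differences in each direction among those measured on all arrays of both groups, and up to 5 per direction with the largest "at least" folds. Where fewer than 5 were called, the 5 with the smallest p per direction are named. miR-363 and its cluster are named always, and so are 2 to 4 members of each list. The alternatives covered the scaling, the background correction, the floor, the filter on dim probes, the value per miRNA, the authors' table, the moderation of the variances, blocks for replicate number and slide row, the arrays in the model, separate control arrays for the overlaps, and leaving out each untreated array in turn. The background correction by normexp (offset 50) was planned on the mean spot signal, which these files do not give, and was run on the median spot signal.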

Results

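The series profiled miRNAs in mammospheres, a culture form that enriches for cells with stem-like properties, from 3 breast lines and from MCF7 treated with either of 2 drugs. Its title concerns miR-363-3p in the maintenance and drug resistance of breast cancer stem cells. There were 2 untreated arrays each for MCF10A, MCF7 and MDA, 1 array for MCF7 with paclitaxel, which stabilises microtubules, and 1 for MCF7 with 5FU, an inhibitor of thymidylate synthase. Of 1205 human miRNAs, 320 were tested. Replicate arrays correlated at r = 0.964 for MCF10A, 0.975 for MCF7 and 0.935 for MDA, across miRNAs, which are not independent replicates. Between the 2 arrays of a line, 44, 21 and 88 miRNAs in the same order of lines lay more than 2-fold apart. Levels below are log2 of the scaled signal, and differences are log2 with the standard error (SE) of the model. For each line, 2 arrays limit the precision.

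miR-363-3p, the miRNA of the title, was not well above background on either MCF10A array, on either MDA array or on MCF7 replicate 1. It was well above background on MCF7 replicate 2, where its level was −1.23, on the paclitaxel array (−1.35) and on the 5FU array (−1.37). On MCF7 replicate 2 all 20 spots of its brighter probe were above background, with a mean intensity of 723 (SD 42.9), against 14.1 (SD 6.04) and none of 20 spots on MCF7 replicate 1. A second probe for the same miRNA gave 531 and 10.3 on these arrays. miR-363-3p was not called in any comparison. The difference was 2.27 (SE 1.59, adjusted p = 0.337) for MCF7 against MCF10A and −2.27 (SE 1.59, adjusted p = 0.339) for MDA against MCF7, and no difference could be measured between MDA and MCF10A. Against untreated MCF7 it was 2.16 with paclitaxel and 2.14 with 5FU, both with an SE of 1.95 and an adjusted p of 1.

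These values rested on which untreated MCF7 array was used. MCF7 replicate 2 alone lay at least 20.1-fold above MCF10A and at least 16.6-fold above MDA, and without replicate 1 the differences with the drugs became −0.12 (paclitaxel) and −0.13 (5FU). Without replicate 2 no difference could be measured between MCF7 and MCF10A, since all these arrays stood at the floor, and the paclitaxel array lay at least 17.8-fold above replicate 1. Before the floor, the brighter probe averaged 14.1 on MCF7 replicate 1. On the MCF10A arrays it averaged 0.42 (replicate 1) and −1.11 (replicate 2). The test passed against MCF10A and MDA without replicate 1, and for both drugs without replicate 2, but in these fits the remaining pairs, MCF10A and MDA, stood wholly at the floor and left a residual SD of 0, so a pass there rests on no measured spread of miR-363-3p. Arrays not above background stood at the floor in the model, so its differences for miR-363-3p depend on the floor. Of the other measured members of its X-linked cluster, miR-18b-5p and miR-20b-5p were not called in any comparison. miR-19b-3p and miR-92a-3p, which are also encoded by the miR-17-92 cluster, were called only between MDA and MCF7. They were higher in MDA by 1.40 (SE 0.32, adjusted p = 0.0368) and 1.63 (SE 0.35, adjusted p = 0.0322).

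**Figure D1:**
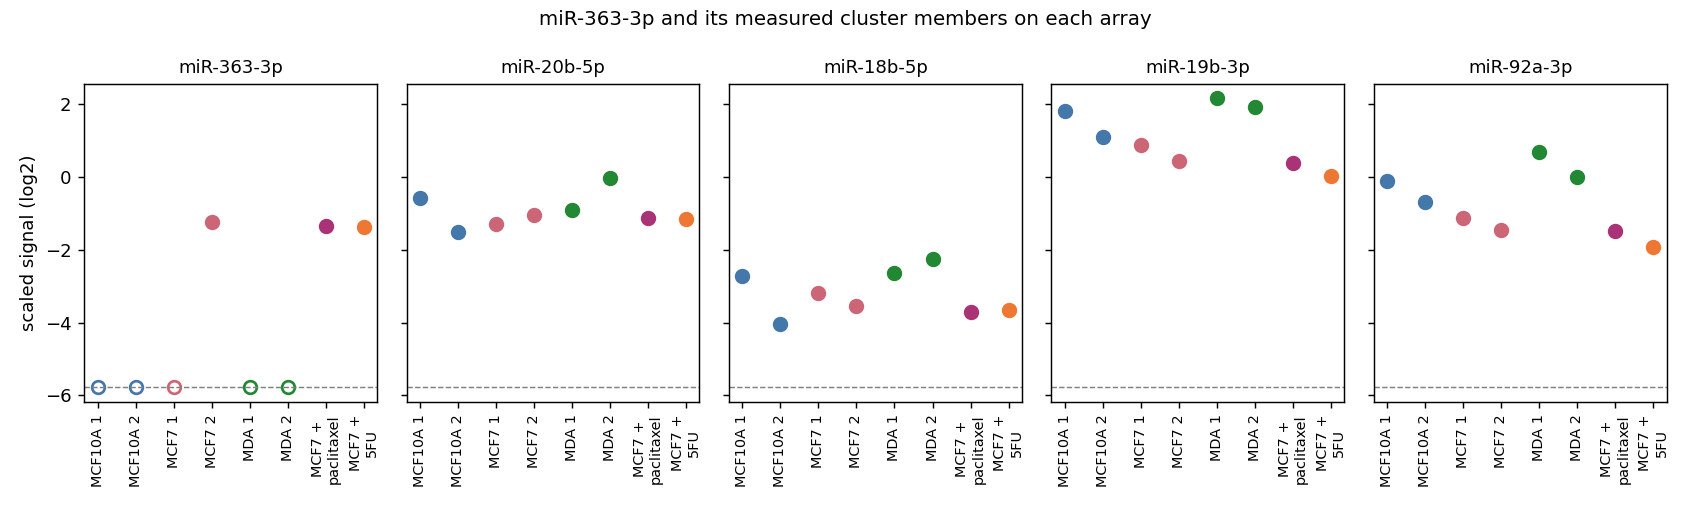
Level (log2 scaled signal) of miR-363-3p and 4 measured members of its cluster on each of the 8 arrays; filled points are well above background, open points are not, and the dashed line is the floor at −5.78. miR-363-3p is above background on MCF7 replicate 2 and on both drug arrays, at −1.23, −1.35 and −1.37, and on no other array.

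MCF7 mammospheres differed from those of the non-tumour MCF10A line in 107 of the 320 miRNAs, 50 higher and 57 lower. This balance turned with the setting: it was 58 higher and 40 lower with quantile normalization, 74 and 51 with the values of the authors, 27 and 15 without MCF7 replicate 1, and 21 and 70 without MCF10A replicate 2 and MDA replicate 1, an alternative chosen after seeing the data because both arrays stood apart in the GC-rich entries. The epithelial miRNAs miR-429 and miR-200a-3p, the luminal-associated miR-342-3p, and miR-7-5p were higher in MCF7. miR-221-3p, miR-222-3p, miR-31-5p, miR-205-5p, miR-100-5p, miR-125b-5p and miR-29a-3p were lower. miR-342-3p stood at 2.34 ± 0.25 in MCF7 against −1.96 ± 0.27 in MCF10A (SD, n = 2 each), a 19.7-fold difference (SE 0.24 on the log2 scale, adjusted p = 0.00163). miR-221-3p, which targets the cell cycle inhibitor p27 and the oestrogen receptor, was at least 67.7-fold lower in MCF7 (adjusted p = 0.000456).

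Among called miRNAs measured on all 4 arrays, the largest differences upward in MCF7 were those of miR-7-5p (5.03, SE 0.66), miR-342-3p (4.30, SE 0.24), miR-429 (3.93, SE 0.16) and miR-200a-3p (3.78, SE 0.16). miR-454-3p, miR-301a-3p, miR-200b-3p, miR-149-5p, miR-195-5p and miR-193a-3p followed, at 3.38 or less. The largest downward were those of miR-100-5p (−4.64, SE 0.35), miR-125b-5p (−3.65, SE 0.37), miR-762 (−3.54, SE 0.34) and miR-29a-3p (−3.41, SE 0.29). miR-642b-3p, miR-150-3p, miR-1181, miR-3656, miR-29b-3p and miR-1915-3p lay between −2.72 and −2.32. In 32 of the called miRNAs one line was below background. Of these, miR-342-5p was at least 13.5-fold, miR-152 at least 4.44-fold, miR-489 at least 3.76-fold, miR-7-1-3p at least 3.48-fold and miR-9-5p at least 3.25-fold higher in MCF7. miR-130a-3p was at least 46.1-fold, miR-224-5p at least 36.8-fold, miR-146a-5p at least 30.3-fold and miR-31-5p at least 27.4-fold lower.

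By list, 11 of 24 differed between MCF7 and MCF10A, 6 higher and 5 lower; with an estimated correlation their adjusted p lay between 0.490 and 0.537 and none was called, while fry called 15, among them these 11. In the miR-200 family, which represses the mesenchymal factors ZEB1 and ZEB2, 5 of 9 measured members were higher and 4 were not called, and the count was 5 adjusted over the list alone (adjusted p = 0.00466; adjusted p = 0.537 with an estimated correlation). Its called members were both arms of miR-200a and of miR-200b, and miR-429, while miR-141-3p (0.05, SE 0.12) and miR-200c-3p (−0.06, SE 0.19) were not called. The luminal list had 2 of 3 members higher, both arms of miR-342, and miR-375 (adjusted p = 0.0727) was not called; adjusted over the list alone all 3 were called (adjusted p = 0.0126; adjusted p = 0.490 with an estimated correlation). In the miR-15/16 family 4 of 10 were higher, the same count adjusted over the list alone, among them miR-195-5p (2.85) and miR-16-2-3p (1.41) (adjusted p = 0.0253; adjusted p = 0.490 with an estimated correlation). This call was lost without MCF10A replicate 1 (adjusted p = 0.0522) or MCF7 replicate 1 (adjusted p = 0.0505).

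In the miR-106b-25 cluster 2 of 3 were higher, miR-25-3p (1.69) and miR-106b-5p (1.69), and 3 adjusted over the list alone (adjusted p = 0.0444; adjusted p = 0.537 with an estimated correlation). This call was lost without any 1 of the untreated arrays other than MCF7 replicate 2 (adjusted p = 0.0627 to 0.0890). In the epithelial cluster of miR-183, miR-96 and miR-182, 1 of 5 was higher, miR-183-5p (0.81), and 3 adjusted over the list alone (adjusted p = 0.0428; adjusted p = 0.537 with an estimated correlation); the call was lost without MCF10A replicate 1 (adjusted p = 0.0890) or MCF7 replicate 1 (adjusted p = 0.0704). A list of neuronal miRNAs had 3 of 4 members higher, miR-9-5p, miR-219-5p and miR-128, and 4 adjusted over the list alone (adjusted p = 0.0126; adjusted p = 0.490 with an estimated correlation).

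Of the lists lower in MCF7, the miR-221 and miR-222 list had 3 of 3 members lower, also adjusted over the list alone, with miR-222-3p at least 24.7-fold lower (adjusted p = 0.0177; adjusted p = 0.490 with an estimated correlation). The list of squamous and basal epithelial miRNAs had 4 of 5 lower, the same count adjusted over the list alone (adjusted p = 0.00876; adjusted p = 0.537 with an estimated correlation). Among them miR-31-3p was at least 18.3-fold lower and miR-205-5p, at the floor on 1 of 2 MCF7 arrays, was lower by an amount that depends on the floor, while miR-203 was not called. In the miR-29 family, which targets collagens, 4 of 6 were lower, the same count adjusted over the list alone (adjusted p = 0.0209; adjusted p = 0.537 with an estimated correlation). In the miR-23/27/24 clusters 5 of 7 were lower, among them miR-24-3p (−1.58) and miR-27b-3p (−1.42), and 6 adjusted over the list alone (adjusted p = 0.0253; adjusted p = 0.490 with an estimated correlation). A list of 21 short GC-rich entries of low conservation, whose signal often varies with RNA handling, had 10 lower and 12 adjusted over the list alone, such as miR-762 and miR-3656 (adjusted p = 0.000576; adjusted p = 0.537 with an estimated correlation). Its median level was −1.83 and −0.90 on the MCF10A arrays and −3.74 and −2.85 on the MCF7 arrays. Probes for viral miRNAs, which stayed outside the tests, were also more often above background on MCF10A replicate 2, with 25 names against 13 on replicate 1.

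With only the major arm of each member, the adjusted p was 0.0504 for the miR-200, squamous and basal, miR-29, miR-15/16 and miR-23/27/24 lists, 0.125 for the miR-183 cluster and 0.0534 for the miR-106b-25 cluster, and none of these was called. With slide row as a block it was 0.0515 for the miR-183 cluster and 0.0549 for the miR-106b-25 cluster. Lists not called between MCF7 and MCF10A still held called members. In the let-7 family, let-7b-5p (−2.18) and let-7c (−1.75) were lower among 11 members, and in the miR-30 family miR-30a-5p (−1.57) and miR-30e-5p (−0.60) among 8. Of the 7 p53-induced miRNAs, 3 were higher, such as miR-192-5p (0.96) and miR-194-5p (0.94), and miR-34b-5p (−0.88) was lower. miR-21-5p was higher by 0.82. None of 9 entries that are fragments of other small RNAs was called.

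Of the 107 calls, 27 remained without any single one of the 6 untreated arrays, among them miR-342-3p, miR-429, miR-200a-3p, miR-301a-3p, miR-149-5p, miR-100-5p, miR-29a-3p, miR-221-3p, miR-130a-3p, miR-31-5p and miR-205-5p. The count fell without either MCF10A array and without either MCF7 array. For 14 of the 107 calls, miR-31-5p among them, 2 of the 3 untreated pairs stood at the floor and add no spread, so calls kept among them rest on at most 1 pair.

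MDA mammospheres lacked the signal of most epithelial miRNAs that MCF10A had. miR-205-5p was at least 641-fold, miR-141-3p at least 371-fold, miR-200c-3p at least 224-fold, miR-203 at least 50.7-fold and miR-31-5p at least 21.4-fold lower in MDA, with no MDA array above background for any of them. miR-99a-5p, miR-100-5p, miR-30a-5p and miR-221-3p were higher in MDA, though each of these calls was lost in some fits without an untreated array. In all, 48 of 320 miRNAs differed, 15 higher and 33 lower. This balance was 17 higher and 17 lower with quantile normalization, and without MDA replicate 2 most calls were higher. miR-99a-5p stood at −0.06 ± 0.03 in MDA against −3.22 ± 0.69 in MCF10A (SD, n = 2 each), an 8.89-fold difference (SE 0.36 on the log2 scale, adjusted p = 0.0138).

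Among miRNAs measured on all 4 arrays, miR-99a-5p (3.15), miR-100-5p (3.12), miR-30a-5p (2.28), miR-30a-3p (2.07) and miR-221-3p (2.03) were higher by the most, followed by miR-4324, miR-140-3p, miR-221-5p, miR-130a-3p and miR-324-5p from 1.44 down to 0.72. miR-183-5p (−2.86, SE 0.21), miR-96-5p (−2.74, SE 0.16), miR-182-5p (−2.26, SE 0.27) and miR-193b-3p (−2.15, SE 0.27) were lower by the most. miR-34a-5p, miR-34b-5p, miR-150-3p, miR-361-3p, miR-342-3p and miR-186-5p followed, between −1.90 and −1.21. miR-10a-5p was at least 6.35-fold, miR-138-5p at least 6.23-fold, miR-551b-3p at least 5.24-fold, miR-455-3p at least 2.98-fold and miR-503 at least 2.68-fold higher in MDA, with no MCF10A array above background.

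By list, 9 of 24 differed between MDA and MCF10A, 4 higher and 5 lower; with an estimated correlation their adjusted p lay between 0.591 and 0.613 and none was called, while fry called 11, among them 7 of these 9 but neither the GC-rich list (adjusted p = 0.265) nor the miR-17-92 cluster (adjusted p = 0.323). In the miR-200 family 6 of 9 members were lower, the same count adjusted over the list alone, with miR-200b-3p at least 17.8-fold and miR-200a-3p at least 7.06-fold lower (adjusted p = 0.000155; adjusted p = 0.591 with an estimated correlation). The squamous and basal list had 4 of 5 lower and 5 adjusted over the list alone (adjusted p = 7.57e-05; adjusted p = 0.591 with an estimated correlation). In the miR-183 cluster 3 of 5 were lower, the same count adjusted over the list alone (adjusted p = 0.0230; adjusted p = 0.613 with an estimated correlation), a call lost without MCF10A replicate 2 (adjusted p = 0.0508) or MDA replicate 2 (adjusted p = 0.0643). Of the p53-induced miRNAs 3 of 7 were lower, miR-34a-5p, miR-34a-3p and miR-34b-5p, and 6 adjusted over the list alone (adjusted p = 0.0175; adjusted p = 0.613 with an estimated correlation); the call was lost without MDA replicate 1 (adjusted p = 0.0911).

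Higher in MDA was the miR-99a, miR-100 and miR-125b list, with 2 of 4 members higher and 4 adjusted over the list alone (adjusted p = 0.00264; adjusted p = 0.591 with an estimated correlation). miR-125b-5p, at 1.69 (SE 0.37, adjusted p = 0.0585), was among those not called. In the miR-221 and miR-222 list 2 of 3 were higher, the same count adjusted over the list alone (adjusted p = 0.0230; adjusted p = 0.591 with an estimated correlation). The cluster of miR-424 and miR-450 had 1 of 5 higher, miR-503, and 2 adjusted over the list alone (adjusted p = 0.0447; adjusted p = 0.591 with an estimated correlation). Its call was lost without MCF10A replicate 1 (adjusted p = 0.155), MCF7 replicate 1 or 2 (adjusted p = 0.0610 each) or MDA replicate 2 (adjusted p = 0.155), and with quantile normalization (adjusted p = 0.0645) or the mean of all probes (adjusted p = 0.0605). The miR-17-92 cluster was higher as a list with none of 8 members called, also adjusted over the list alone (adjusted p = 0.0447; adjusted p = 0.613 with an estimated correlation), and this was lost without MCF10A replicate 2 (adjusted p = 0.246) or MDA replicate 2 (adjusted p = 0.517), and with major arms only (adjusted p = 0.0820). The GC-rich list was lower with none of 21 members called, also adjusted over the list alone (adjusted p = 0.0230; adjusted p = 0.613 with an estimated correlation), and this was lost without MCF10A replicate 2 (adjusted p = 0.275) or MDA replicate 2 (adjusted p = 0.293). Its median level was −1.80 and −2.47 on the MDA arrays, where 16 and 11 viral names were above background.

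Of the 48 calls, 11 remained without any single one of the 6 untreated arrays: miR-205-5p, miR-141-3p, miR-200c-3p, miR-200a-3p, miR-31-5p, miR-31-3p, miR-183-5p, miR-96-5p, miR-361-3p, miR-138-5p and miR-455-3p. The count was 30 with slide row as a block and 19 with only the arrays of these lines. Leaving out either MCF7 array repeats that last fit for this contrast, since only the spread of the MCF7 pair is lost. The count also fell without either MCF10A array. For 9 of the 48 calls, 2 of the 3 untreated pairs stood at the floor and add no spread. Among the 11 kept, these include miR-31-5p, miR-31-3p, miR-138-5p and miR-455-3p, so their being kept rests on the spread of at most 1 pair.

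**Figure D2:**
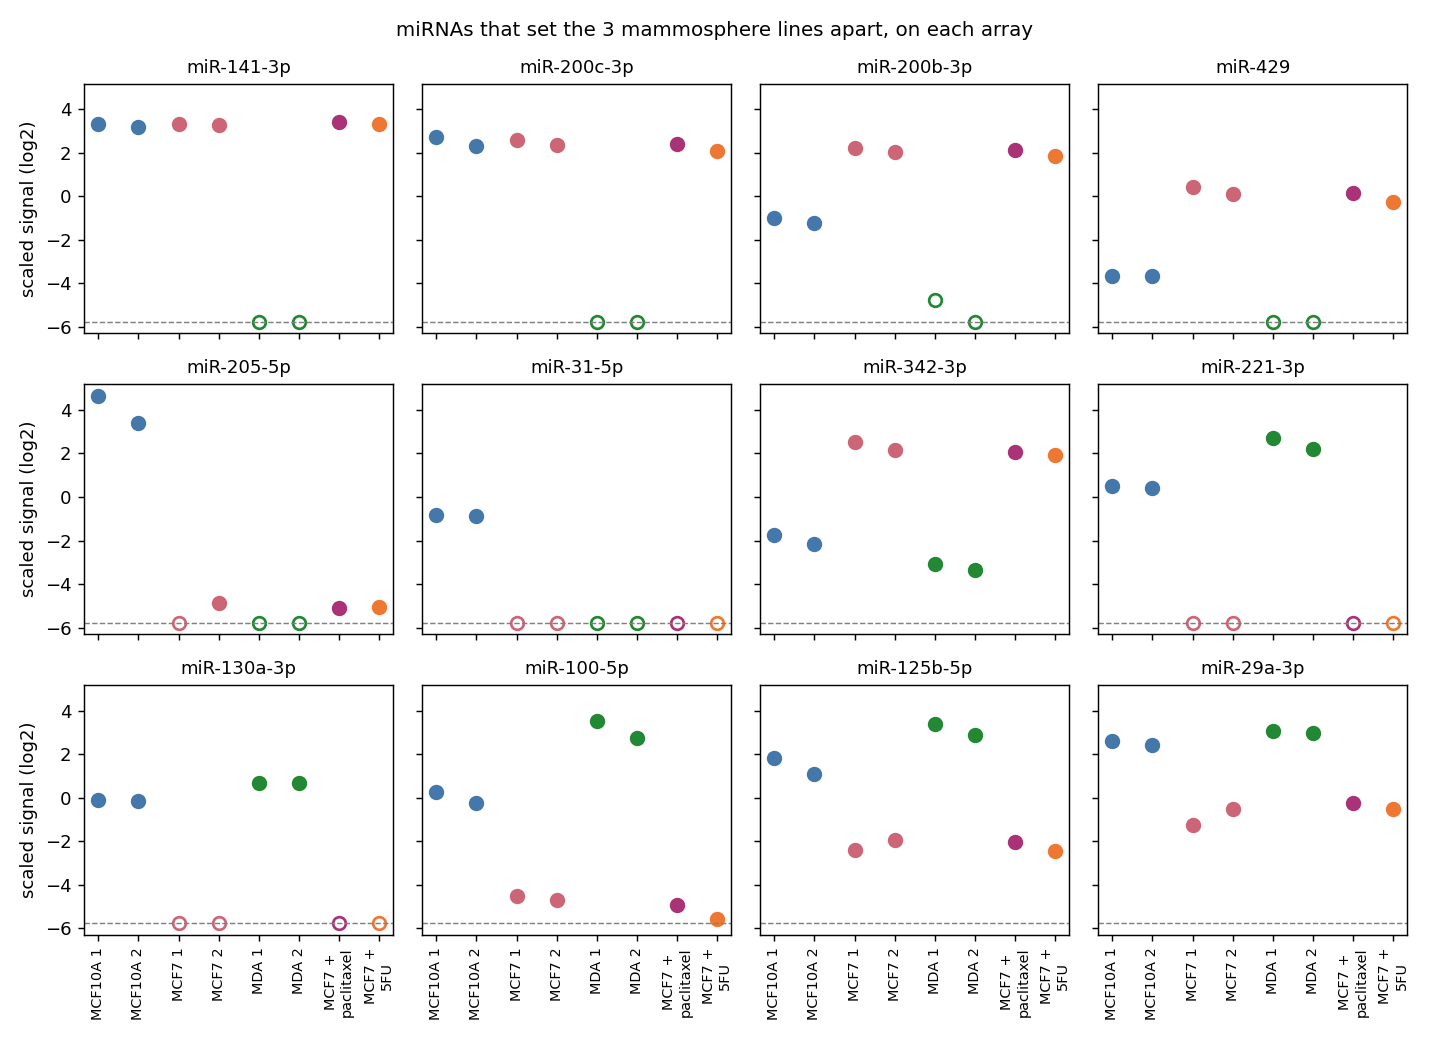
Level (log2 scaled signal) of 12 miRNAs on each of the 8 arrays; filled points are well above background, open points are not, and the dashed line is the floor at −5.78. miR-141-3p and miR-200c-3p are above background on all MCF10A and MCF7 arrays and on no MDA array, and miR-31-5p is above background on the MCF10A arrays only.

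MDA and MCF7 mammospheres, both from tumour lines, differed in 115 of 320 miRNAs, 49 higher and 66 lower in MDA. This balance turned to 76 higher and 60 lower without MDA replicate 2, and to 35 and 19 without MCF10A replicate 2 and MDA replicate 1, an alternative chosen after seeing the data. miR-221-3p was at least 276-fold, miR-130a-3p at least 80.1-fold and miR-222-3p at least 74.1-fold higher in MDA, and miR-100-5p was 217-fold higher (7.76, SE 0.35, adjusted p = 0.000572). miR-141-3p was at least 383-fold, miR-200c-3p at least 215-fold, miR-200b-3p at least 167-fold, miR-200a-3p at least 97.1-fold and miR-429 at least 46.5-fold lower. miR-342-3p was 47.5-fold lower (−5.57, SE 0.24, adjusted p = 0.000515), at −3.23 ± 0.21 in MDA (SD, n = 2).

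Beside miR-100-5p, the miRNAs measured on all 4 arrays with the largest differences upward were miR-125b-5p (5.33, SE 0.37), miR-29a-3p (14.9-fold, SE 0.29 on the log2 scale), miR-30a-5p (3.85, SE 0.35) and miR-181a-5p (2.86, SE 0.64). miR-99a-5p, miR-29b-3p, miR-181b-5p, miR-1181 and miR-29c-3p followed, from 2.81 down to 2.04. Downward, miR-342-3p was followed by miR-7-5p (−4.44, SE 0.66), miR-183-5p (−3.67, SE 0.21), miR-193b-3p (−3.58, SE 0.27) and miR-96-5p (−3.30, SE 0.16). miR-301a-3p, miR-182-5p, miR-149-5p, miR-365a-3p and miR-1260b lay between −3.23 and −2.37. miR-224-5p was at least 11.8-fold and miR-4324 at least 8.44-fold higher in MDA, with no MCF7 array above background.

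By list, 10 of 24 differed between MDA and MCF7, 5 higher and 5 lower; with an estimated correlation their adjusted p lay between 0.434 and 0.517 and none was called, while fry called 16, among them 8 of these 10 but neither the GC-rich list (adjusted p = 0.102) nor the miR-17-92 cluster (adjusted p = 0.0742). Of the miR-200 family 8 of 9 were lower in MDA and 9 adjusted over the list alone (adjusted p = 1.59e-06; adjusted p = 0.434 with an estimated correlation). All 3 luminal miRNAs were lower, also adjusted over the list alone, miR-342-5p by at least 11.1-fold and miR-375 by at least 9.06-fold (adjusted p = 0.00996; adjusted p = 0.434 with an estimated correlation). In the miR-183 cluster 4 of 5 were lower, the same count adjusted over the list alone (adjusted p = 0.00996; adjusted p = 0.434 with an estimated correlation). Of the p53-induced miRNAs 6 of 7 were lower, the same count adjusted over the list alone, among them miR-34a-5p (−1.37) and miR-192-5p, at the floor on 1 of 2 MDA arrays (adjusted p = 0.0115; adjusted p = 0.476 with an estimated correlation). The neuronal list had 3 of 4 lower, miR-128 (−2.13), miR-219-5p and miR-9-5p, and 4 adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.434 with an estimated correlation).

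Of the lists higher in MDA, the miR-29 family had 6 of 6 members higher, also adjusted over the list alone (adjusted p = 0.00996; adjusted p = 0.451 with an estimated correlation), a call lost without MDA replicate 2 (adjusted p = 0.0644). In the miR-221 and miR-222 list 3 of 3 were higher, also adjusted over the list alone (adjusted p = 0.00996; adjusted p = 0.434 with an estimated correlation). The miR-99a, miR-100 and miR-125b list had 3 of 4 higher and 4 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.434 with an estimated correlation). The miR-17-92 cluster had 2 of 8 higher, miR-92a-3p and miR-19b-3p, the same count adjusted over the list alone (adjusted p = 0.0493; adjusted p = 0.517 with an estimated correlation). That call was lost without MCF7 replicate 2 (adjusted p = 0.0941) or MDA replicate 2 (adjusted p = 0.306), and with major arms only (adjusted p = 0.0732). The GC-rich list had 3 of 21 higher and 2 adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.517 with an estimated correlation), lost without MDA replicate 1 (adjusted p = 0.0734).

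Among lists not called between MDA and MCF7, the miR-181 family had 3 of 5 members higher (adjusted p = 0.0620), with miR-181b-5p at 2.20 beside miR-181a-5p. The miR-15/16 family had 2 of 10 higher and 5 lower, among them miR-195-5p, at the floor on MDA replicate 1, and miR-497-5p, at the floor on both MDA arrays, so the sizes of these differences depend on the floor. miR-21-5p was 3.02-fold lower in MDA (−1.59, adjusted p = 0.00257).

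Of the 115 calls, 43 remained without any single one of the 6 untreated arrays, among them those of miR-221-3p, miR-130a-3p, miR-100-5p, miR-125b-5p, miR-29a-3p, miR-30a-5p, miR-342-3p, miR-141-3p and miR-200c-3p. The count was 75 without either MCF10A array and 57 without either MCF7 array.

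Against MCF10A, 15 miRNAs differed the same way in MCF7 and in MDA. miR-324-5p was higher in both, by 1.16 (SE 0.12) and 0.72 (SE 0.12). The 14 lower in both included miR-205-5p, miR-135b-5p, both arms of miR-31, let-7b-5p and let-7c, miRNAs of the let-7 family that are low in stem cells, miR-361-3p, miR-27b-3p and miR-34b-5p. let-7b-5p differed by −2.18 (SE 0.20) in MCF7 and −1.13 (SE 0.20) in MDA, the latter with an adjusted p of 0.0405. Several of these shared calls held in few settings. For a given contrast some of the alternatives counted next are the same fit, such as those without either array of the line outside it. Over 23 alternatives, those without an array among them, the call in MDA stayed in 1 for let-7c, 1 for miR-27b-3p, 8 for let-7b-5p, 8 for miR-34b-5p and 8 for miR-324-5p, and the call in MCF7 in 2 for miR-34b-5p. Without each untreated array in turn, let-7c, miR-27b-3p and miR-135b-5p in MDA and miR-34b-5p in MCF7 were called in 0 of 6 fits. Independent lists of these sizes would share 2.34 higher and 5.88 lower, and unchanged groups set against the same MCF10A arrays shared 0.01 on average in 100 simulations. No miRNA differed in those simulations, so few calls could be shared. Their count therefore cannot show how many shared calls the common MCF10A arrays give when many miRNAs are called. A further 14 miRNAs were called in opposite directions, and fewer were so with a separate MCF10A array for each line. The stability of these calls varied. Over the alternatives, the call in MDA stayed in 3 of 23 for miR-342-3p and 3 of 22 for miR-221-5p. It stayed in 22 of 23 for miR-183-5p and 21 of 22 for miR-200a-3p. Across miRNAs the log2 differences of both comparisons had r = 0.237 (0.501 in the simulations) and a covariance of 0.591 (0.126 in the simulations). With a separate MCF10A array for each line, an alternative chosen after seeing the data, 7 miRNAs (MCF7 against replicate 1) or 6 (MCF7 against replicate 2) were called the same way, with r of 0.231 and 0.122 and covariances of 0.586 and 0.331. The count of 15 was 9 without MCF10A replicate 1, 6 without MCF10A replicate 2 and 7 without either MCF7 array. It was 1 for miRNAs above background on all 8 arrays, and 34 without MCF10A replicate 2 and MDA replicate 1, an alternative chosen after seeing the data.

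Paclitaxel and 5FU were each given to MCF7 mammospheres to ask how miRNAs of the drug-exposed cells differ. No single miRNA passed the limma test in either. At the preset correlation the p53-induced miRNAs were higher as a list on both drug arrays and the miR-200 family was lower as a list with 5FU. With an estimated correlation these calls did not hold (adjusted p = 0.659 and 0.798 for the p53-induced list, 0.816 for miR-200), and fry called no list in any drug comparison. miR-34a-3p, the minor arm of a p53-induced precursor, differed by 1.83 (SE 0.31) with 5FU and 0.60 (SE 0.31) with paclitaxel, with adjusted p of 0.338 and 1. With 1 array per drug, drug and array cannot be separated.

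For paclitaxel, 3 miRNAs had an unadjusted p under 0.05 and the smallest adjusted p was 1. The smallest p-values upward belonged to miR-373-5p (0.78), miR-15a-5p (0.65), miR-361-3p (0.49), miR-34b-5p (0.74) and miR-4317 (0.79), and downward to miR-3200-3p (−0.64), miR-421 (−0.76), let-7d-3p (−0.31), miR-454-5p (−0.48) and miR-324-5p (−0.31). None of these passed, and miR-3200-3p and let-7d-3p stood at the floor on the paclitaxel array. The count of 0 was 1 with the floor doubled (miR-142-3p), 2 with no filter on dim probes (let-7d-3p and miR-215) and 1 without MCF7 replicate 2 (miR-363-3p); miR-142-3p was named after its value was seen. In each of these fits at least 4 untreated arrays stood at the floor for the miRNA and its residual SD was 0.00324 or less, so these calls depend on the floor.

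For 5FU, 19 miRNAs had an unadjusted p under 0.05 and the smallest adjusted p was 0.338. The smallest p-values upward belonged to miR-373-5p (1.23, SE 0.17), miR-34a-3p, miR-663a (1.15, SE 0.21), miR-215 (0.65, SE 0.13) and miR-342-5p (0.71, SE 0.15). Downward they belonged to miR-200b-5p (−0.90, SE 0.16), miR-9-5p (−0.71, SE 0.13), miR-149-5p (−1.69, SE 0.34), miR-200a-5p (−0.71, SE 0.16) and miR-454-5p (−0.84, SE 0.21), all with adjusted p from 0.338 to 0.449. The count of 0 was 3 with the floor doubled (miR-373-5p, miR-215 and miR-9-5p), 5 with no filter on dim probes (miR-215, miR-33b-5p, let-7d-3p, miR-339-3p and miR-9-5p) and 1 without MCF7 replicate 2 (miR-363-3p). miR-33b-5p and miR-339-3p were named after their values were seen. In each of these fits at least 3 untreated arrays stood at the floor for the miRNA, with a residual SD of 0.0203 or less. All 6 untreated arrays stood there for miR-33b-5p, and with the floor doubled for miR-373-5p and miR-215, with a residual SD of 0. These calls too depend on the floor.

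For the mean of both drugs the limma test called 0, with 15 at an unadjusted p under 0.05 and a smallest adjusted p of 0.588. miR-373-5p (1.01), miR-34a-3p (1.22) and miR-34b-5p (0.94) were among the smallest p-values upward, and miR-200b-5p (−0.56) and miR-149-5p (−0.96) among those downward. The count was 2 with the floor doubled (miR-373-5p and miR-9-5p), 3 with no filter on dim probes (miR-215, miR-33b-5p and let-7d-3p) and 1 without MCF7 replicate 2 (miR-363-3p). Between 5FU and paclitaxel it called 0, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.981. Here miR-663a (1.12), miR-34a-3p (1.23) and miR-342-5p (0.87) had the smallest p-values upward among others, and miR-9-5p (−0.87) and miR-149-5p (−1.47) downward. The count was 4 with the floor doubled (miR-142-3p, miR-215, miR-373-5p and miR-9-5p) and 4 with no filter (miR-215, miR-339-3p, miR-33b-5p and miR-9-5p). These calls, for the mean and between the drugs, depend on the floor as those above do.

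The p53-induced list of 7 miRNAs was higher with paclitaxel (adjusted p = 2.82e-05; adjusted p = 0.659 with an estimated correlation) and with 5FU (adjusted p = 6.82e-07; adjusted p = 0.798 with an estimated correlation). None of its members was called in either comparison; adjusted over the list alone, none was called with paclitaxel and 3 were higher with 5FU. On the mean of both drug arrays its members miR-34a-3p (1.22), miR-34b-5p (0.94), miR-34a-5p (0.70), miR-192-5p (0.51), miR-215 (0.45) and miR-194-5p (0.37) all lay above the untreated mean, and miR-34c-5p was at the floor. At the preset correlation the list was also called higher with 5FU than with paclitaxel, by a median of 0.39, with none of 7 called, also adjusted over the list alone. This sets 1 array against 1, with no spread between samples of either group, so it describes these arrays only. The call was lost with an estimated correlation and with slide row as a block. Within slide rows, the median of the list was 0.87 for 5FU against MCF7 replicate 1 and 0.26 for paclitaxel against MCF7 replicate 2. The untreated arrays themselves differed by 0.33 in the median of this list, replicate 2 above replicate 1.

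**Figure D3:**
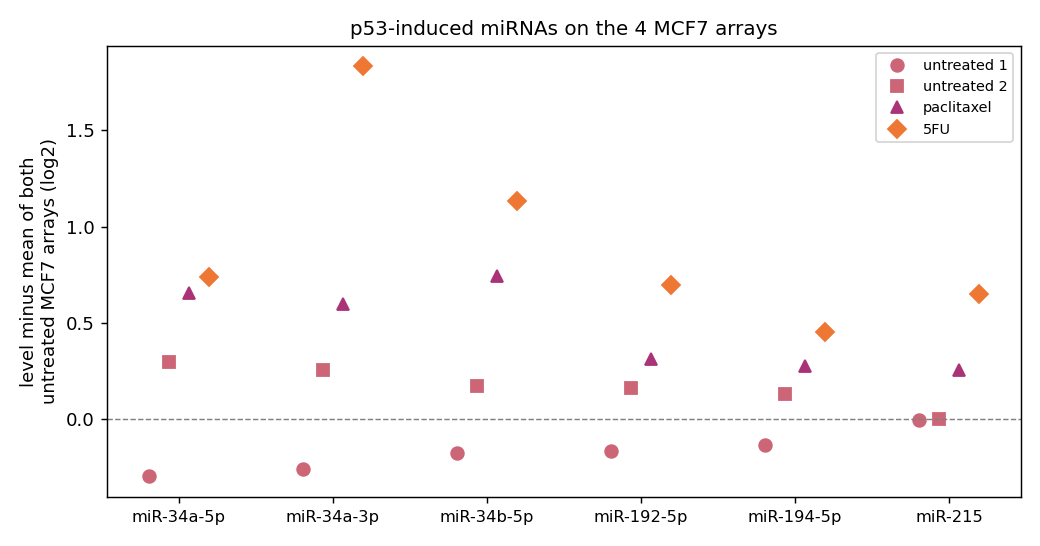
Level of 6 p53-induced miRNAs on the 4 MCF7 arrays, as log2 difference from the mean of both untreated arrays. The paclitaxel array is above the untreated mean by 0.60 and the 5FU array by 1.83 for miR-34a-3p, and both drug arrays lie above that mean for each of the 6 miRNAs.

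The miR-200 family was lower as a list with 5FU (adjusted p = 0.00319; adjusted p = 0.816 with an estimated correlation), with none of 9 called and 2 lower adjusted over the list alone. When each member was represented by its major arm only, the adjusted p was 0.380, with differences for the major arms of −0.53 for miR-429, −0.40 for miR-200c-3p, −0.29 for miR-200b-3p, 0.04 for miR-141-3p and 0.01 for miR-200a-3p, none of them called. A list of 3 tumour-promoting miRNAs, miR-21-5p, miR-21-3p and miR-373-5p, was higher with paclitaxel (adjusted p = 0.0367; adjusted p = 0.659 with an estimated correlation) and 5FU (adjusted p = 0.0212; adjusted p = 0.798 with an estimated correlation). None of the 3 was called, and 1 was higher in each adjusted over the list alone. The paclitaxel call was lost without any 1 of the untreated arrays other than MCF7 replicate 2 (adjusted p = 0.0528 to 0.0875), and the 5FU call without MCF7 replicate 1 (adjusted p = 0.0742). With slide row as a block neither was called (adjusted p = 0.127 and 0.0612), and with quantile normalization the 5FU call was lost (adjusted p = 0.0563). The GC-rich list was higher with 5FU, with none of 21 called, also adjusted over the list alone (adjusted p = 0.00811; adjusted p = 0.818 with an estimated correlation), and this was lost without MCF7 replicate 1 (adjusted p = 0.101) and with quantile normalization (adjusted p = 0.0563).

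For the mean of both drugs, 4 lists were called with none of their members called. The p53-induced list was higher (adjusted p = 4.63e-07; adjusted p = 0.866 with an estimated correlation), with 3 members adjusted over the list alone. The tumour-promoting list was higher (adjusted p = 0.0199; adjusted p = 0.866 with an estimated correlation), with 1 adjusted over the list alone; it was lost without MCF7 replicate 1 (adjusted p = 0.116) or either MDA array (adjusted p = 0.0572). The miR-200 family was lower (adjusted p = 0.0199; adjusted p = 0.866 with an estimated correlation), with 0 adjusted over the list alone, and its median of −0.33 became 0.19 with no scaling. It was lost without MCF7 replicate 1 (adjusted p = 0.116) or either MDA array (adjusted p = 0.0706), and with major arms only (adjusted p = 0.660). The miR-17-92 cluster was lower (adjusted p = 0.0446; adjusted p = 0.866 with an estimated correlation), with 0 adjusted over the list alone, and its median of −0.43 became 0.06 with no scaling. It was lost without MCF7 replicate 1 (adjusted p = 0.821), MCF7 replicate 2 (adjusted p = 0.0811) or either MDA array (adjusted p = 0.174), and with major arms only (adjusted p = 0.119).

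The comparison of 5FU with paclitaxel sets 1 array against 1, with no spread between samples of either group, so the lists below describe these 2 arrays. At the preset correlation 4 lists besides the p53-induced one were called, each with an adjusted p of 0.636 with an estimated correlation and none of their members called. The GC-rich list was higher on the 5FU array (adjusted p = 0.000430), and the miR-200 family (adjusted p = 0.000488) and the miR-15/16 family (adjusted p = 0.00152) were lower, each with 0 members adjusted over the list alone. The neuronal list was lower with 1 of 4 adjusted over the list alone, miR-9-5p (adjusted p = 0.00660), and this was lost with slide row as a block (adjusted p = 0.123). The miR-200 call was lost with the major arm of each member only (adjusted p = 0.123).

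No miRNA was called under both drugs in the limma model. The log2 differences of the 2 drugs correlated at r = 0.674 across miRNAs (0.327 in simulations of unchanged groups against the same untreated arrays), with a covariance of 0.122 against 0.123 in the simulations. With a separate untreated MCF7 array for each drug, an alternative chosen after seeing the data, r fell to 0.221 (paclitaxel against replicate 1) or 0.0132 (paclitaxel against replicate 2), the covariance to 0.056 or 0.0032, and 0 miRNAs were shared. The overlap was 2 with no filter on dim probes (let-7d-3p and miR-215) and 1 without MCF7 replicate 2 (miR-363-3p), calls that depend on the floor.

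Few markers of cell types other than breast epithelium were measured. Of 7 muscle and 2 liver miRNAs on the array none was above background on any array, and of 9 stromal miRNAs 2 were above background on at least 1 array and none was tested. Of the haematopoietic markers, miR-451a was above background on the 2 drug arrays only and miR-142-3p on MCF7 replicate 2 and both drug arrays, at levels of −4.81, −4.45 and, at the floor, −5.78. miR-150-3p was above background on all 8 arrays and was lower than in MCF10A in MCF7 (−2.65) and MDA (−1.53). Only these 3 of the 11 haematopoietic entries on the array were above background on any array. The other arm of miR-150 was not among them, so miR-150-3p alone does not show that blood cells were present. The endothelial marker miR-126-3p was at −1.91 and −2.14 on the MCF7 arrays, and was higher in MCF7 than in MCF10A, where 1 of 2 arrays stood at the floor. The hypoxia-induced miR-210 differed within the MCF7 pair, at −2.66 on replicate 1 and −0.01 on replicate 2, and was not called between MCF7 and MCF10A (1.23, adjusted p = 0.392). It was at −0.24 on the paclitaxel array and −1.21 on the 5FU array.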

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

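Of the tests in this part, those of the GC-rich entries, of RNA of another line and of scaling were chosen after the result was seen, as were the comparison between the drug arrays and the estimated correlation set beside the p53-induced list.

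The effects of MCF7 and of MDA against MCF10A went in opposite directions for 14 miRNAs, and the difference between these effects is the limma contrast of MDA against MCF7. The miRNAs were chosen for their opposite calls, so that this contrast called all 14 follows from the choice and adds no evidence. The difference, as log2 of MDA minus MCF7, was 8.24 for miR-221-3p, 7.76 for miR-100-5p, 6.46 for miR-130a-3p, 3.85 for miR-30a-5p, 3.21 for miR-4324 and 2.99 for miR-221-5p. It was −7.39 for miR-200b-3p, −7.09 for miR-200a-3p, −6.03 for miR-429, −5.57 for miR-342-3p, −3.67 for miR-183-5p, −3.58 for miR-193b-3p, −1.72 for miR-4306 and −1.59 for miR-21-5p. Values with 1 line at the floor depend on the floor, and folds for those are given above as lower bounds. Some of the 14 opposite calls held in few settings, as given above.

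miR-363-3p was above background on 1 of the 2 untreated MCF7 arrays. Lower sensitivity of the MCF7 replicate 1 array was argued against, since 100% of the 22 miRNAs of like level on replicate 2 were above background on replicate 1. RNA of another line on that array was argued against too, since its r with replicate 2 exceeded its highest r with an MCF10A or MDA array by 0.179. That replicate 2 was a drug-treated culture stays open. On it 6 of 7 p53-induced miRNAs were lower than on both drug arrays, but the median gap to paclitaxel (0.26) was smaller than that between the drug arrays (0.39). Replicate 2 correlated at 0.993 with paclitaxel and 0.987 with 5FU against 0.975 with replicate 1. Replicate 1 correlated at 0.979 with paclitaxel and 0.966 with 5FU, and 6 of 7 were lower on it as well. Being nearer to paclitaxel than to the other untreated array thus does not single out replicate 2. For 5FU this held only for replicate 2 (0.987), since replicate 1 was nearer to replicate 2 (0.975) than to 5FU (0.966). A difference between the MCF7 cultures or stocks stays open too and was not tested.

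The GC-rich entries differed within pairs of untreated arrays, with 17 of 21 higher in slide row 2 in the MCF10A pair and 17 of 21 in the MDA pair. Brightness of the array was argued against, since in the MDA pair the brighter array had the lower median, by −0.656. Slide row stays open. In the MCF7 pair row 2 was higher by 0.309, against the 0.328 set as the bound. The SE of 0.215 was taken over the 21 entries, as if independent, and holds no spread between samples. Paclitaxel (row 2) minus 5FU (row 1) was −0.391, a pair that also differs in drug. Breakdown of the RNA cannot be told apart either, since the fragments of other small RNAs moved by −1.04 in the MCF10A pair but only 6 of 9 were lower there. No biological explanation was tested.

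The p53-induced list was higher on both drug arrays, which a response to either drug may give. Chance stays open: the list median lay at percentile 100 of 10000 random lists of miRNAs of like level, but such lists lack the correlation between members. In camera with an estimated correlation the adjusted p was 0.866, but at 3 residual degrees of freedom that version has little power and cannot decide. Scaling and processing stay open as well, since the median of 0.506 was 0.222 with normexp and 0.41 with the values of the authors, and 0.546 to 1.03 with 3 other scalings. Whether untreated replicate 1 sets the difference stays open: against replicate 2 alone the median was 0.403. Its SE of 0.153 was taken over the 7 members, as if independent, and holds no spread between samples. With 1 array per drug, drug and array cannot be separated.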

How the results depend on the processing

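The model and most alternative settings were fixed before the data were examined; leaving out MCF10A replicate 2 with MDA replicate 1, which stood apart in the GC-rich entries, leaving out the GC-rich and fragment entries, separate control arrays, and, for the lists, slide row and leave-one-out were chosen after seeing the data. No called named miRNA changed sign, but with no scaling the medians of the miR-200 family (−0.33 to 0.19) and the miR-17-92 cluster (−0.43 to 0.06) did for the mean of both drugs. Of 3824 values of called named miRNAs under the alternatives, 2607 (68.2%) stayed called and 1217 did not, with 32 of 170 called in all. Signal over background limits the dim miRNAs: 52 to 83 of 320 were at the floor on each array. For the changes below, the cause was not tested, with 1 exception. A fit without an untreated array outside a line comparison keeps its differences and changes only the residual spread.

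The counts of called miRNAs are given in the order MCF7 against MCF10A (107), MDA against MCF10A (48), MDA against MCF7 (115) and the overlap of both lines against MCF10A (15). They were 65, 25, 71 and 6 when scaled over all human probes, 62, 26, 74 and 9 with no scaling, and 70, 25, 61 and 7 with normexp. They were 26, 14, 35 and 6 with no filter on dim probes, and 50, 10, 45 and 1 for miRNAs above background on all 8 arrays. With the floor doubled, MCF7 against MCF10A gave 64 and MDA against MCF7 gave 74. MDA against MCF10A gave 31 with the mean of all probes, 26 with the total gene signal (overlap 6), 30 with slide row as a block (overlap 6) and 19 with only the arrays of the 2 groups, where MDA against MCF7 gave 75. With a block for replicate number MDA against MCF10A gave 26 (overlap 5). The differences of replicate 2 from replicate 1 correlated across miRNAs at 0.44 between MCF10A and MCF7. They correlated at −0.34 between MCF10A and MDA and −0.04 between MCF7 and MDA. Slide row runs opposite to replicate number in MDA, so these values cannot decide whether the numbers pair the samples. Taken by slide row these correlations were 0.44, 0.34 and 0.04, so an effect of slide row over all miRNAs stays open. Without MCF10A replicate 2 and MDA replicate 1, MDA against MCF7 gave 54 and the overlap 34. With a separate MCF10A array for each line the overlap was 7 or 6. Without the GC-rich and fragment entries the counts were 102, 50, 114 and 16.

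The drug counts, 0 in the limma model, became 1 (paclitaxel), 3 (5FU), 2 (mean) and 4 (5FU against paclitaxel) with the floor doubled, and 2, 5, 3 and 4 with no filter, with an overlap of 2 between drugs. Each of these calls is of a miRNA at the floor on at least 3 untreated arrays and depends on the floor. Of 45 list calls, 0 held in camera with an estimated correlation. With 3 residual degrees of freedom that version has little power. It did not call even the miR-200 family in MDA against MCF7, with 8 of 9 members called lower. Lost were 19 with fry, 13 of 37 with the major arm of each member, 6 with slide row as a block, 3 with quantile normalization and 1 with the mean of all probes.

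Leaving out each untreated array in turn gave 39 to 132, 15 to 70 and 57 to 136 called miRNAs for the 3 line comparisons and an overlap of 6 to 18. It gave 0 to 1 for paclitaxel, 5FU, the mean and their overlap, 0 for 5FU against paclitaxel, and 34 to 44 list calls. A lone array left in a group was assumed to vary like the other groups, which for miR-363-3p stood at the floor and left a residual SD of 0 without either MCF7 array. With arrays below background at the floor, on which its values depend, miR-363-3p ranged from 0 to 4.54 for MCF7 against MCF10A, −4.54 to 0 for MDA against MCF7, −0.12 to 4.43 for paclitaxel, −0.13 to 4.41 for 5FU and −0.13 to 4.42 for the mean. It stayed at 0 for MDA against MCF10A and −0.02 for 5FU against paclitaxel.

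The median log2 difference over all miRNAs, −0.19 for MCF7 against MCF10A and 0.31 for MDA against MCF7, became 0.01 and 0 when scaled over all human probes. With no scaling it was 0.43 for paclitaxel, 0.22 for 5FU and 0.33 for the mean, and with the values of the authors 0.14, 0.12 and 0.11 for the line comparisons. The share of calls that were higher also moved. For MCF7 against MCF10A, 46.7%, it was 56.9% when scaled over all human probes, 59.2% with quantile normalization and with the values of the authors, 61.5% with no filter, 34.3% with normexp and 32% for miRNAs above background on all 8 arrays. It was 64.3% and 63.3% without MCF7 replicate 1 and 2, and 23.1% without MCF10A replicate 2 and MDA replicate 1. For MDA against MCF10A, 31.3%, it was 44% scaled over all human probes, 50% with quantile normalization, 44.7% with the values of the authors, 21.1% with only the arrays of the 2 groups or without either MCF7 array, 20% without MCF10A replicate 2 and 52.9% without MDA replicate 2. For MDA against MCF7, 42.6%, it was 31.4% with no filter, 22.8% and 24.6% without MCF7 replicate 1 and 2, 55.9% without MDA replicate 2 and 64.8% without MCF10A replicate 2 and MDA replicate 1, so in these last 2 most calls were higher.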

Other observations

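No test in this part was chosen after the result was seen, since it reports values without tests. The untreated MCF7 arrays differed beyond miR-363-3p. Replicate 2 minus replicate 1 was 4.54 for miR-363-3p, 3.09 for miR-630, 2.89 for miR-1246, 2.65 for miR-210, 2.47 for miR-1290, 2.04 for miR-4299, 1.90 for miR-135b-5p and −1.58 for miR-18a-5p. miR-363-3p, miR-630 and miR-135b-5p were not above background on replicate 1, so their differences and rank depend on the floor. The paclitaxel array was nearer to replicate 2 than to replicate 1 for 179 of 320 miRNAs (55.9%) and the 5FU array for 195 (60.9%). Ties count here as not nearer to replicate 2, so the remaining miRNAs were not all nearer to replicate 1. Of the 320, 70 stood at the floor on replicate 1 and 66 on replicate 2, and those at the floor on both are ties. The correlation across miRNAs was 0.993 with replicate 2 and 0.979 with replicate 1 for paclitaxel, and 0.987 and 0.966 for 5FU.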
